A study of Mus musculus with 2 samples.

How the data were processed

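Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark laid down along the bodies of transcribed genes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse lung on postnatal day 0. Per the labels, the tissue was healthy lung pooled from male and female mice of a C57BL/6N-type stock, and there were 2 biological replicates of this one condition. The labels give 15 mice for the pool of replicate 1, and the number for replicate 2 was not given in the sources used here. The deposited file records state that replicate 1 was made from technical replicate 1, and replicate 2 from technical replicates 1 and 2 together.

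The analysis started from 4 peak lists deposited by the authors in narrowPeak format on the mm10 build. Per the deposited file records, the authors called peaks on each replicate separately and on both replicates pooled, and derived a replicated list from those 3 lists. The rule for keeping a replicated peak was not given in the sources used here, and neither were the peak caller, its thresholds or the read depth. All 56097 replicated peaks were rows of the pooled list. Each peak carries the authors' fold enrichment, a ratio over a background that the deposited records do not define, which was read as such from the deposited format. It also carries the -log10 of the authors' p-value and the -log10 of their q-value, as deposited. These scores were used only to describe, rank or filter peaks within a list. Because peaks were the only data used, a gene without a peak is a gene whose signal did not pass the authors' threshold, not a gene shown to lack the mark.

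Gene positions came from GENCODE mouse release M21, which is on the same assembly as the peak lists, and chromosome lengths and runs of N from the GRCm38 sequence. On 0 chromosomes did a peak run past the chromosome end. Peaks on chromosomes 1 to 19, X and Y were used, and peaks on unplaced scaffolds were counted but left out of the gene measurements. For each of 21911 protein-coding genes, the share of its span, from annotated start to end, that lay under peaks was computed in each replicate. A gene was called marked when at least 10% of its span was covered in each of the 2 replicates. Where genes overlap, a peak counts for each of them, since peaks carry no strand. A few annotated spans run through several neighbouring genes because of readthrough transcripts, and these are named where they occur.

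Overlap between replicates required at least 1 shared base and was set beside 100 circular shifts of a list along each chromosome, with runs of N left out. The same kind of shift gave the coverage expected in genes, exons, introns, promoters (1 kb on either side of a protein-coding start), intergenic sequence and the 10 kb flanks of genes. Profiles used 20 equal bins along genes of at least 5 kb. Agreement between replicates was described by Spearman's rho and Pearson's r over genes, without a p-value, since genes are not replicates. With a single condition there was no comparison between groups and no p-value was computed. Shares of peaks are given with 95% Wilson intervals, which cover counting error only.

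The 31 gene lists, the level of 10%, all but 2 of the alternatives and the rule for naming genes were fixed before the data were examined. A list's median coverage was given as its percentile among 10000 random lists of as many protein-coding genes, matched on gene length in 20 bins, separately in each replicate. This percentile describes these libraries and is not a p-value. Because many medians were 0, percentiles of list means are given as well, an addition made after seeing the data. The genes named were, of each list, the 2 with the highest mean coverage and, for lists of cell types of the lung, the 2 with the lowest; the 20 protein-coding genes with the most bases under replicated peaks; the genes holding the 10 replicated peaks with the highest fold enrichment; the 10 genes of at least 10 kb that differed most between replicates in each direction after equalising peak numbers; and every member of the list of H3K36 methylation enzymes and readers. Genes named outside this rule are identified as chosen after their values were seen.

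The alternatives kept only peaks with a -log10 p of at least 5, took equal numbers of the strongest peaks, joined peaks within 1 kb, required 50% of a peak's bases for overlap, set the gene level at 5% or 20%, used the replicated or pooled list or the 3' side of each gene alone, left out overlapping or short genes, dropped length matching, and left out each replicate. The computation of gene coverage was checked on simulated data over 21911 genes, with a single list. Of 50 genes each planted with 15%, 30% and 50% coverage, 50 were called at every size, and 6 of 50 were called at 5%. Planted coverage above the level of 10% is called by definition, so these counts check the arithmetic and not the sensitivity. In the same test, 1823 of 21711 genes without planted coverage were called over circularly shifted replicate 1 peaks. Of 200 random gene lists, 6 fell outside the central 95% of length-matched lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.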

Results

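H3K36me3 was mapped by ChIP-seq in the lungs of newborn mice, on postnatal day 0, in 2 biological replicates, each a pool of lungs from both sexes. The peak list of replicate 1 held 144321 peaks with a mean width of 462 bp ± 332 (SD over peaks) and covered 66.7 Mb, or 2.52% of the sequenced genome. The list of replicate 2 held 62660 peaks with a mean width of 311 bp ± 136 and covered 19.5 Mb, or 0.737% of the genome. Replicate 1 therefore had 2.30 times as many peaks and 3.42 times as many covered bases. The authors' q-value was 0.05 or lower for 95.6% of replicate 1 peaks but only 49.7% of replicate 2 peaks. Many replicate 2 peaks are thus weak calls. The authors' list on pooled reads held 145955 peaks, of which 56097 were kept as replicated, with a median width of 591 bp. The read depth behind each list is unknown. Coverage values below are given as replicate 1 and then replicate 2, because their level differs with the size of the lists, and no comparison between conditions was possible.

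The first question was where in the genome of newborn lung the mark lay. Peaks lay almost entirely inside genes. Annotated genes of any type held 96.6% of the bases under replicate 1 peaks and 96.1% of those under replicate 2 peaks. Peaks covered 5.27% of genic bases in replicate 1 and 0.160% of intergenic bases, and 1.54% and 0.0535% in replicate 2. The ratio of genic to intergenic coverage was 30.8 ± 2.97 (SD, n = 2). Relative to 100 circular shifts, coverage of genes was 2.0 and 2.0 times the shifted mean, and coverage of intergenic sequence was 0.0672 and 0.0769 times the shifted mean. Exons were covered to 13.4% and 4.43%, and introns to 4.32% and 1.20%. Within 1 kb of the starts of protein-coding genes, coverage was 0.478% and 0.222%, or 0.175 and 0.273 times the shifted mean. Intergenic sequence within 10 kb downstream of protein-coding genes was covered to 1.77% and 0.485%, and within 10 kb upstream to 0.411% and 0.134%. Intergenic sequence more than 10 kb from any gene was covered to 0.00740% and 0.0112%.

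Along genes, coverage was low at the start and rose toward the 3' end. Among 2038 marked genes of at least 5 kb, mean coverage in the first of 20 bins was 0.921% in replicate 1 and 0.659% in replicate 2. It reached its maximum of 59.3% in bin 15 in replicate 1 and of 26.7% in bin 18 in replicate 2, and was 45.9% and 19.4% in the last bin. The downstream 50% of these genes was covered to 55.6% and the upstream 50% to 26.1% in replicate 1, a ratio of 2.13. In replicate 2 the values were 23.4% and 9.50%, a ratio of 2.47. The mean ratio was 2.30 ± 0.241 (SD, n = 2). The 15741 other genes of at least 5 kb had ratios of 2.58 and 2.81 at lower coverage. Exons of marked genes were covered more than their introns, by 1.33 and 1.62 times. Within the downstream 50% of these genes the ratios were 1.14 and 1.36.

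**Figure D1:**
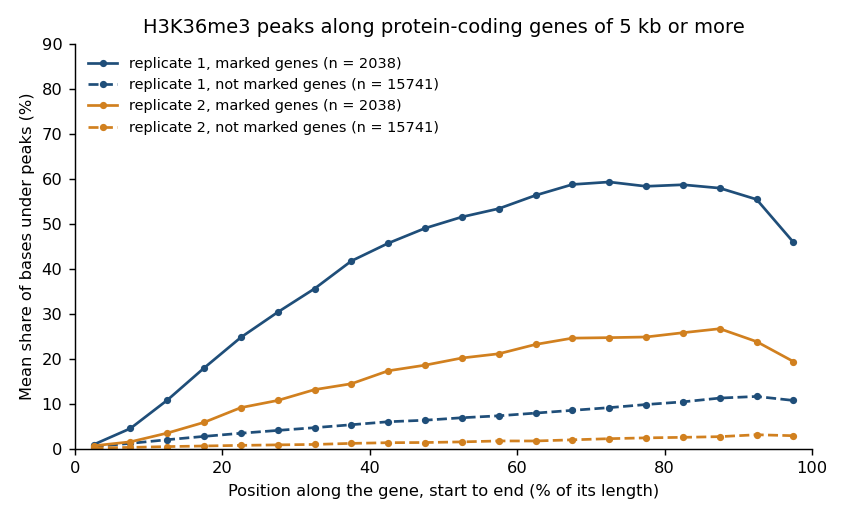
Mean share of bases under H3K36me3 peaks (y axis, percent) in 20 equal bins from the annotated start to the end of protein-coding genes of at least 5 kb (x axis, percent of gene length). Colours give the replicate, solid lines the 2038 marked genes and dashed lines the 15741 other genes; coverage of marked genes rises from below 1% in the first bin to 59.3% in replicate 1 and 26.7% in replicate 2.

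The 10 strongest replicated peaks, ranked by the authors' fold enrichment, lay in Plec, Shroom3, Tpm1, Zfp810, Myh9, Zfp26, Lrrfip1, Eif3a and Tln1. The strongest lay near the 3' end of Plec (ENSMUSG00000022565.15), which encodes the cytoskeletal linker plectin, at chromosome 15, 76171876 to 76182410 (mm10). It was 10535 bp wide with a fold enrichment of 8.16, and 93.9% of its bases were exonic. It was also the widest replicated peak. Plec spans 76170974 to 76232574 on the minus strand and was covered to 32.5% and 24.9%. A second peak in Plec had a fold enrichment of 7.18. The peak in Shroom3, an actin-binding protein, had a fold enrichment of 7.34, was 95% exonic and lay at chromosome 5, 92939895 to 92943309. Peaks in Tpm1 (tropomyosin), Myh9 (a non-muscle myosin heavy chain) and Tln1 (talin) had fold enrichments of 7.14, 7.02 and 6.69. The zinc finger genes Zfp810 and Zfp26 held peaks with fold enrichments of 7.05 and 6.95, and the Zfp810 peak was 100% exonic. The Zfp26 peak also lay in the overlapping gene Gm26733. The remaining peaks of the 10 lay in Lrrfip1 and in Eif3a, a translation initiation factor, each with a fold enrichment of 6.69.

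**Figure D2:**
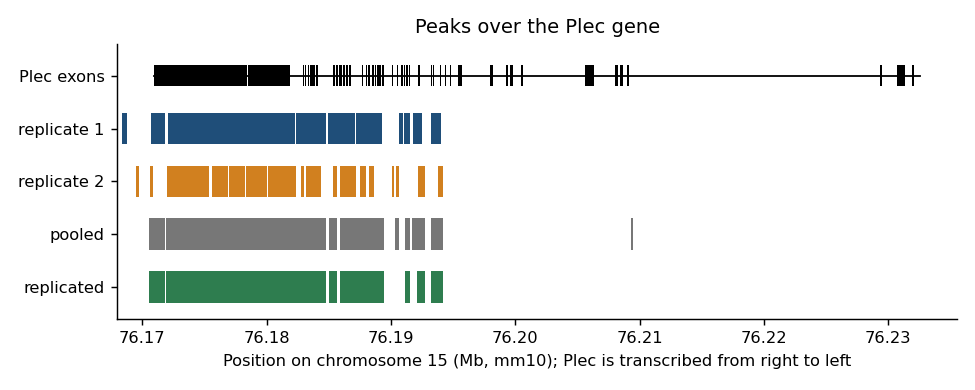
Map of Plec on chromosome 15 (x axis, position in Mb, mm10), with its exons in the top row and the peaks of replicate 1, replicate 2, the pooled list and the replicated list below as bars drawn to scale. Plec is read from right to left, and most peaks lie over its 3' part; a pooled peak lies further upstream, and some replicate peaks lie past the annotated end.

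The next question was which genes carried the mark in both pools. Of 21911 protein-coding genes, 2214 (10.1%) were marked, against a mean of 466.5 and at most 589 when both lists were shifted together. Their median coverage was 39.9% and 14.9%. Another 10523 genes (48.0%) had no base under a peak in either replicate. The share marked was highest, 17.2%, among genes of 10 to 20 kb, and 1.24% among genes of 100 kb or more. Replicate 2 set the count: 2263 genes reached 10% in replicate 2 and 6513 in replicate 1. Of the 2263, 97.8% also reached it in replicate 1. Marked genes that overlapped no other annotated gene numbered 1017. The count was 476 at a level of 20% of the span, 4304 at 5%, 517 with only peaks of -log10 p of at least 5, 4602 with the replicated list and 6581 with the pooled list.

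Genes were also ranked by their bases under replicated peaks, a measure that favours long genes. Ubr4, a ubiquitin ligase on chromosome 4 (139352609 to 139489588), had 89.6 kb under replicated peaks and was covered to 66.5% and 29.2%. Macf1, a cytoskeletal crosslinker, had 88.4 kb, and Vps13d, a lipid transfer protein, had 68.6 kb. Trrap, a component of histone acetyltransferase complexes, had 59.6 kb and was covered to 70.8% and 24.5%. Rnf213, Wdfy3, Syne2, Chd2, Herc2 and Ubr2 had between 53.2 kb (Ubr2) and 58.6 kb (Rnf213). Tns1, Sptbn1, Pcnt, Abca1, Gtf3c1, Dync1h1, Mtor and Sptan1 had between 43.9 kb (Sptan1) and 45.8 kb (Tns1). Dync1h1, the dynein heavy chain, was covered to 69.1% and 32.3%, and the growth kinase gene Mtor to 47.0% and 17.8%. Sptan1, which encodes a spectrin, was covered to 71% and 36.3%. Wdfy3 and Syne2 were at 9.69% and 7.93% in replicate 2 and so were not marked. Gm20388 (216.1 kb under replicated peaks) and Fgfr2 (62.8 kb) complete the 20, but their annotated spans of 4435 kb and 2961 kb run across other genes, whose peaks they include.

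Housekeeping, ribosomal protein, complex I and zinc finger genes were covered more than random lists of their length. All 22 housekeeping genes had a peak in replicate 1 and 11 were marked, with median coverage of 43.2% and 10.8% against random medians of 0.959% and 0. Eif4g2, a translation initiation factor, was covered to 69.9% and 36.2%, and the elongation factor gene Eef2 to 62.8% and 37.9%. Of 80 ribosomal protein genes 28 were marked, with medians of 20.6% and 7.18%; Rps5 reached 71.3% and 13.6% and Rps3 64.9% and 14.4%. Of 36 genes for subunits of respiratory complex I 11 were marked, with medians of 19.2% and 4.80%; Ndufa10 reached 52.3% and 15.4% and Ndufa9 50.4% and 14.2%. Of 365 Zfp zinc finger genes 80 were marked, with medians of 12.2% and 2.76% and means of 16.0% and 5.66%, against random means of 11.5% and 3.66%; Zfp606 reached 67.7% and 40% and Zfp869 74.8% and 31%. The medians of these 4 lists were above those of all 10000 length-matched random lists in each replicate. Without replicate 2 the level of 10% was reached by 20 housekeeping, 56 ribosomal protein, 25 complex I and 195 Zfp genes. With only peaks of -log10 p of at least 5, the medians of the ribosomal protein, complex I and Zfp lists no longer lay above the central 95% in both replicates. At that threshold 5 ribosomal protein, 2 complex I and 29 Zfp genes were still marked, against 517 of all 21911 protein-coding genes. A list median of 0 ranks above no random list, so the change in medians does not show that coverage fell to that of other genes. Of 27 cell division genes 26 had a peak in replicate 1, but only Mcm6, a subunit of the replicative helicase, was marked, at 44.2% and 14.7%. Mcm2 reached 36.2% and 9.64%. The median of this list was above 98.5% and 95.7% of random lists, so in replicate 2 it lay within the central 95%. In replicate 1 alone, 20 of the 27 reached 10%.

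The machinery of the mark itself was covered too. Of 23 H3K36 methylation enzymes and readers, 23 had a peak in each replicate and 8 were marked. Their medians of 25.4% and 6.28% were above those of all 10000 random lists in each replicate. The demethylase gene Kdm4a was covered to 63.6% and 27.5%, the elongation factor gene Supt6 to 58.6% and 24.8%, and Brpf1, which encodes a subunit of an acetyltransferase complex, to 62.1% and 19.6%. Nsd1 was covered to 40.4% and 11.2%, Iws1 to 35.7% and 12.5%, Ash1l to 34.3% and 10.9%, Kdm2a to 30.4% and 10.2%, and Kdm4b to 25.4% and 14.3%. Setd2, the main H3K36 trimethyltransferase gene, at chromosome 9, 110532597 to 110618633, was covered to 33.7% and 7.44% and was not marked. The other members that were not marked ranged in replicate 1 from 1.25% in Phf19 to 32.4% in Psip1. Between these lay Smyd2 (1.88%), Kdm2b (4.68%), Dnmt3b (5.05%), Kdm4c (9.02%), Phf1 (9.96%), Zmynd11 (15.8%), Msh6 (19.2%), Dnmt3a (21.1%), Mtf2 (22.5%), Morf4l1 (25%), Nsd3 (27.6%) and Nsd2 (29.6%). In replicate 1 alone, 17 members reached 10%. Most members of this list, 20 of 23, overlap another annotated gene. With only peaks of -log10 p of at least 5, the housekeeping list and this list alone kept medians above the central 95% of random lists in both replicates.

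Marker genes of lung cell types carried peaks at some members and none at others; a gene said to have no peak had none in the list of either replicate. Of 145 markers in 8 lists, 8 (5.52%) were marked, and 57.2% had a peak in the pooled list. Alveolar type 2 cells had 2 of 18 marked: Fasn, fatty acid synthase (chromosome 11, 120805846 to 120824547), at 64.7% and 46.9%, and Lpcat1, an enzyme of surfactant lipid synthesis, at 32.5% and 14.9%. Cebpa and Lamp3 had no peak in either replicate. Alveolar type 1 cells had 2 of 16 marked: the vascular growth factor gene Vegfa (48.2% and 25.5%) and the receptor gene Ager (22.6% and 10.1%), with no peak at Aqp5 or Igfbp2. The general epithelial list had 1 of 18 marked, the splicing regulator gene Esrp2 (19.7% and 16.1%). Krt18 was at 2.75% and 5.46%, and Cldn4 and Cldn7 had no peak. The endothelial list had 1 of 25 marked, Egfl7 (25.6% and 11.2%). Esam was at 30.2% and 2.42%, and Car4 and Cldn5 had no peak. Of 16 smooth muscle and pericyte genes Mcam (36.8% and 16.4%) and Tagln (32.7% and 12.4%) were marked, and Actg2 and Kcnj8 had no peak. Esrp2, Egfl7 and Tagln share part of their spans with other protein-coding genes, between which peaks cannot be assigned. With equal numbers of peaks from each replicate, Ager and Esrp2 had no coverage in replicate 1 and were not marked. None of 26 mesenchymal genes was marked. The hedgehog receptor gene Ptch1 was at 30.0% and 9.65%, the fibronectin gene Fn1 at 27.6% and 4.42%, and Dcn and Foxf1 had no peak, although 10.3% of Foxf1 lay under a peak of the pooled list. Without replicate 2, the level of 10% was reached by 7 of the 26 mesenchymal, 5 of the 25 endothelial, 4 of the 18 type 2 and 5 of the 16 type 1 genes.

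None of 18 airway secretory and ciliated genes was marked; Rfx3 was at 3.10% and 0.588%, Muc5b at 1.32% and 0, and Bpifa1 and Ccdc40 had no peak. None of 8 mesothelial genes, among them Aldh1a2 and Bnc1, had a peak. The mean coverage of the 145 markers together was 5.78% and 2.0%. Both values were below the central 95% of length-matched random lists, whose means were 9.42% and 2.93%. Their median in replicate 1, 1.39%, was above the random median of 0.768% and at the 72.8th percentile, so the mean and the median fell on opposite sides of the random lists. In replicate 2 both the list's median and the random median were 0.

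The mean coverage of the 53 blood cell markers was 2.42% and 0.404%, below that of the 145 lung markers. This difference was not tested, and it did not hold for every list. In replicate 1 the myeloid mean of 4.44% was above the general epithelial (3.17%), airway (0.309%) and mesothelial means. It was below the means of the other lung lists. The 73 markers of other organs had a mean coverage of 0.0576% and 0.0293%. None of 53 myeloid, lymphoid and erythroid markers was marked, and 22.6% had a peak in the pooled list. Among 19 myeloid genes Cd68 was at 43.5% and 0 and Cx3cr1 at 13.3% and 5.57%, but the annotated span of Cx3cr1, 168.3 kb, overlaps other protein-coding genes, whose peaks it includes. Adgre1 and Cybb had no peak. Of 20 erythroid genes Xpo7, which also overlaps another protein-coding gene, was at 16.0% and 4.98% and the transferrin receptor gene Tfrc at 18.5% and 0.963%, and Ermap and Gata1 had no peak. Of 14 lymphoid genes Ikzf1 (0.533% and 0) and Pax5 (0 and 0.114%) had a peak in a single replicate each, and Bcl11b and Cd19 had none. Of 12 neuroendocrine and neural crest genes only Sox10 had a peak (2.25% and 0); Ascl1 and Calca had none. Of 73 markers of 5 other organs or lineages none was marked and 8.22% had a pooled peak. No peak lay at any of 15 hepatocyte genes, such as Alb and Ahsg, or of 15 skeletal muscle genes, such as Acta1 and Actn3. Of 16 cardiac genes the highest were Myh7 (0.969% and 0) and Mybpc3 (0.675% and 0). Of 15 neuronal genes they were Snap25 (0 and 0.304%) and Stmn2 (0 and 0.138%). Of 12 germ cell genes Sycp3 was highest (2.07% and 1.60%), while Dazl had no peak. Myh7 and Sycp3 share part of their spans with other protein-coding genes, between which peaks cannot be assigned.

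Other gene families ranged from partly covered to empty. Of 19 genes of lung branching signals Notch1 (35.3% and 20.4%) and Ctnnb1, which encodes beta-catenin (33.3% and 16.1%), were marked, and Ctnnb1 overlaps another protein-coding gene. Of 15 imprinted protein-coding genes Igf2r was marked at 30.4% and 10.7%, and Impact was at 20.6% and 8.30%. Igf2r shares part of its span with the antisense transcript Airn, which peaks without strand cannot separate. Neither Hox list, of 15 genes of paralog groups 1 to 5 (such as Hoxa1 and Hoxa2) and 16 of groups 9 to 13 (such as Hoxa10 and Hoxa11), had a peak, and neither did any of 67 replication-dependent histone genes, such as Hist1h1a and Hist1h1b. Of 1092 olfactory receptor genes only Olfr684 had a peak (0 and 2.34%), and Olfr1 had none. Of 326 vomeronasal receptor genes only Vmn2r1 had one (0 and 0.873%), and Vmn1r1 had none. Of 54 clustered protocadherin genes 21 had a peak in each replicate and none was marked; Pcdhgc5 was highest at 11.8% and 5.89%, followed by Pcdhgc4 at 11.6% and 5.70%. The 21 with a peak, all with symbols beginning with Pcdhg, share their 3' exons, so peaks cannot be assigned to a member. By their medians as by their means, 5 of the 31 lists were above the central 95% of random lists in both replicates: housekeeping genes, H3K36 enzymes and readers, ribosomal proteins, complex I subunits and Zfp genes. With the stricter peaks only 2 of them stayed above by their medians, housekeeping genes and H3K36 enzymes and readers. Low medians could not be ranked, because many random lists also had a median of 0. By their means, 16 lists were below the central 95% in both replicates, namely airway, mesothelial, lymphoid, erythroid, neuroendocrine, cardiac, skeletal muscle, hepatocyte, neuronal and germ cell markers, both Hox lists, olfactory and vomeronasal receptors, histones and protocadherins. The 10 others, among them the remaining lung cell types, myeloid cells, cell division, branching signals and imprinted genes, were neither.

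**Figure D3:**
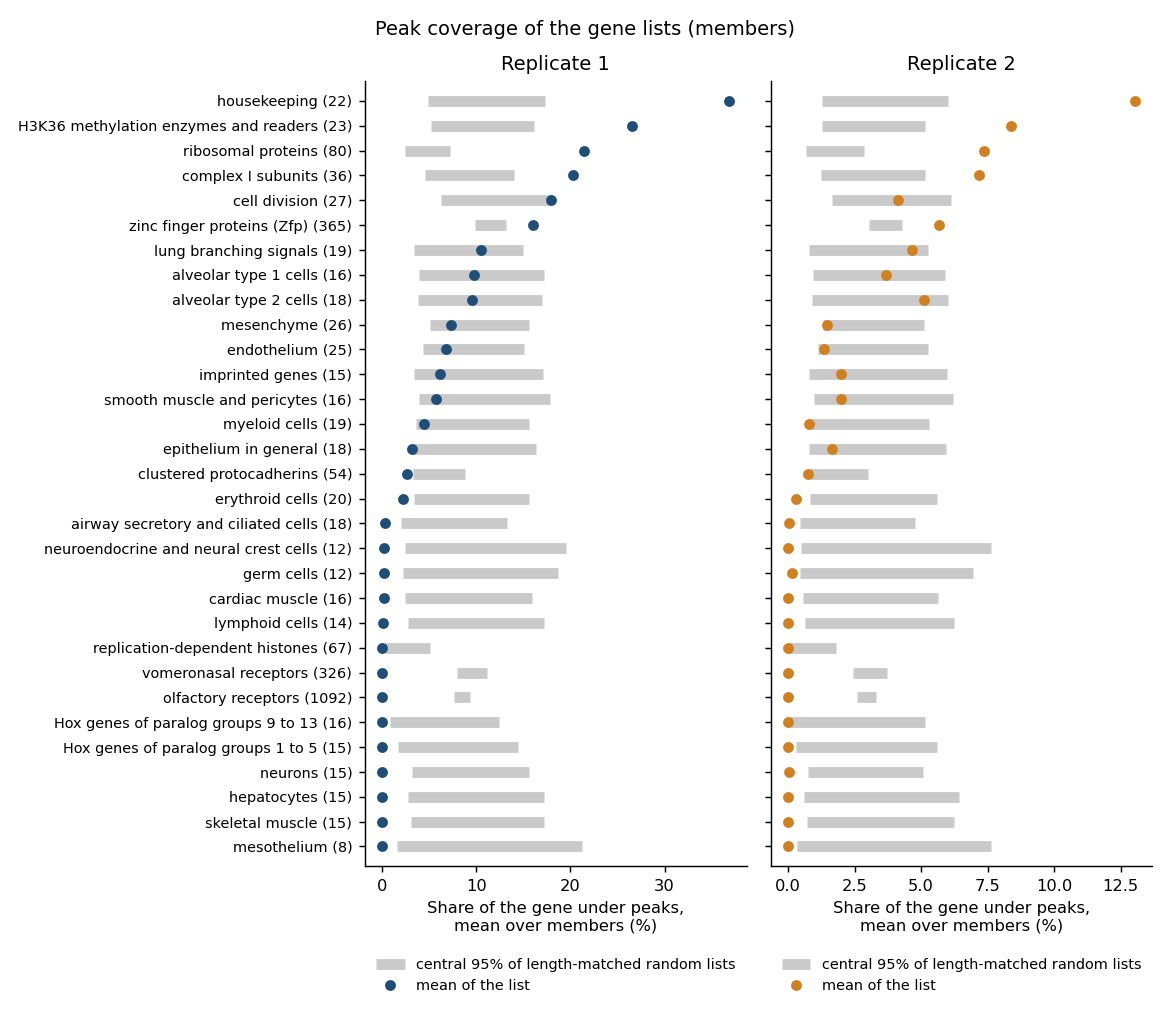
Mean share of the gene under peaks over the members of each of 31 gene lists (x axis, percent; number of members in brackets), in replicate 1 (left) and replicate 2 (right). Grey bars give the central 95% of the means of 10000 length-matched random lists; housekeeping genes, H3K36 enzymes and readers, ribosomal proteins, complex I subunits and zinc finger genes lie to the right of the bar in both replicates.

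Genes on chromosome X were covered far less than genes on autosomes. Peaks covered 0.937% of gene-body bases on X and 6.41% on autosomes in replicate 1, a ratio of 0.146. In replicate 2 the values were 0.0855% and 1.87%, a ratio of 0.0456. The 2 ratios differed by more than 1.5 times, with a mean of 0.0959 ± 0.0711 (SD, n = 2). None of 948 protein-coding genes on X was marked, against 2214 of 20780 (10.7%) on autosomes. A peak was present at 26.5% and 8.02% of X genes and at 51.0% and 44.9% of autosomal genes. Among autosomes coverage ranged from 4.77% (chromosome 6) to 9.0% (chromosome 11) in replicate 1 and from 1.29% (chromosome 14) to 2.77% (chromosome 11) in replicate 2. None of 183 genes on Y was marked.

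**Figure D4:**
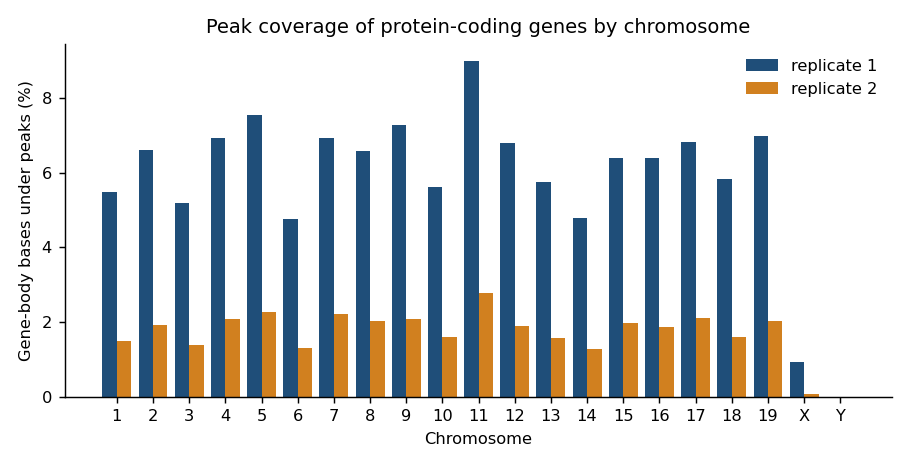
Share of the bases of protein-coding genes under peaks (y axis, percent) on each chromosome (x axis), as bars from 0 for replicate 1 and replicate 2. Chromosome 11 is highest in both replicates (9.0% and 2.77%), X is at 0.937% and 0.0855%, and Y is at 0.

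The last question was how far the pools shared their marked regions. Of replicate 2 peaks 71.6% (95% Wilson interval 71.2 to 71.9%) overlapped a replicate 1 peak, against a mean of 4.45% over shifts. Of replicate 1 peaks 28.6% (28.4 to 28.9%) overlapped a replicate 2 peak, against 1.91%. The shared bases made 16.0% of all bases under either list, against 0.658%. Overlap rose with peak strength, from 13.6% of the weakest 10% of replicate 1 peaks to 61.6% of the strongest, and from 61.7% to 88.0% of replicate 2 peaks. Median width rose as well, from 252 to 744 bp and from 229 to 366 bp, and wider peaks meet the rule of 1 shared base more easily. Over 21911 genes, coverage in the replicates ranked genes alike, with a Spearman's rho of 0.867 and a Pearson's r of 0.860. Genes are not independent replicates, and 48.0% of them were at 0 in both. Over the 11388 genes with a peak in either replicate, rho was 0.790 and r was 0.809. Of the authors' replicated peaks, 66.9% overlapped a peak of each replicate list.

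**Figure D5:**
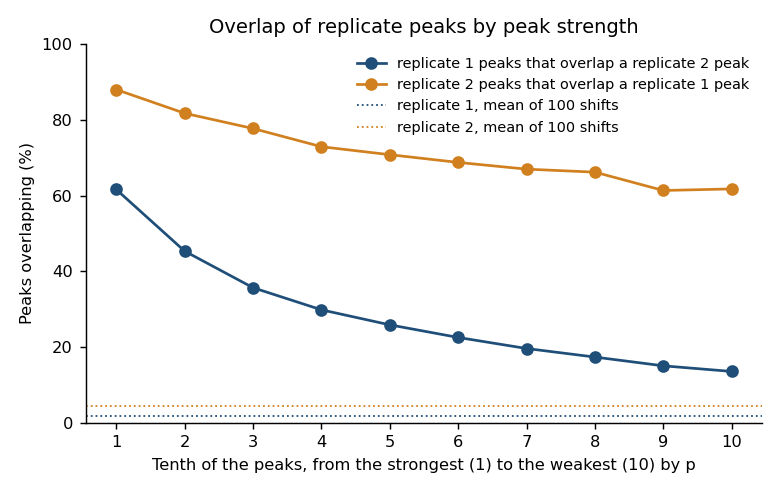
Share of peaks of a replicate that overlap a peak of the other by at least 1 base (y axis, percent), for 10 equal parts of the list from strongest to weakest by the authors' p (x axis). Points are the observed shares and dotted lines the means of 100 circular shifts (1.91% for replicate 1 and 4.45% for replicate 2); the strongest peaks overlap at 61.6% and 88.0%.

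With equal numbers of the strongest peaks, 62654 from each list, replicate 1 still covered genes of at least 10 kb more, at a mean of 6.86% against 3.36%. Differences of more than 10 percentage points were found at 2042 such genes with replicate 1 higher and 12 with replicate 2 higher, of 14151. The largest differences toward replicate 1 were at Anapc2 (58.7% against 13.6%), 2610507B11Rik (66.3% against 22.3%) and Eif4a3, an exon junction complex helicase (49.5% against 5.77%). Erlin2, Rbm22, Ddx17, Ncl, Ddb1, Chd3 and Fus followed, with differences from 40.7 points (Fus) to 43.5 points (Erlin2). Toward replicate 2 the largest were at Mrpl37, a mitochondrial ribosomal protein gene (9.18% against 28.3%), Cacfd1 (3.57% against 20.3%) and Slc35c2 (0 against 16.0%). Helz2, Slc25a44, Pgpep1, Arv1, Lamb2, Gabarapl2 and Polm followed, the last with 10.3% against 20.5%. Equalising removed replicate 1 peaks only. With all peaks, replicate 1 covered these 10 genes more, except Slc35c2 (11.6% against 16.0%) and Pgpep1 (20.2% against 21.4%). Mrpl37 was then at 39.4% against 28.3%. With a single list per pool, no test of these differences was possible.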

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

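Of the tests in this part, the search for replicate 1 genes without coverage in replicate 2, the comparison of lung markers with markers of other organs, and the use of the mean rather than the median in the test of short genes, were chosen after the results had been seen; the bounds of the others were set before their values were computed.

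Some peaks lay outside the protein-coding genes that were measured, and are given because data outside the main measurement held more than the 3 counts that a count of 0 allows, which is no test against an expected number. Intergenic coverage was 0.0672 and 0.0769 of its shifted mean. The replicated list held 1291 peaks that overlapped no annotated gene. Of these, 98.1% had their midpoint within 10 kb downstream of a protein-coding gene, and their median fold enrichment was 3.37 against 3.43 for all replicated peaks. The list also held 5 peaks on unplaced scaffolds. Of 5358 lincRNA genes that lie outside protein-coding genes, 8 (0.149%) were covered to at least 10% in both replicates. They include Malat1, an abundant nuclear RNA (45.1% and 22.8%), and Gm26917 on chromosome 17 (19.4% and 95%), both chosen after their values were seen. Coverage of Gm26917 was higher in replicate 2, although replicate 1 covered more bases, and whether it reflects the mark was not tested.

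Replicate 2 had fewer and narrower peaks than replicate 1. If the pool of replicate 1 held further marked genes, many genes covered in replicate 1 should be nearly empty in replicate 2. Of 5071 genes of at least 10 kb with 10% coverage in replicate 1, 3.23% had under 1% in replicate 2, and in the other direction 0% of 1602 genes did; lower depth in replicate 2 would also leave weakly covered genes empty, so further genes in replicate 1 stay open. For fewer reads or weaker enrichment in replicate 2, the bound set was that 80% or more of the strongest replicate 1 peaks recur. The value was 61.6%, between that bound and the 50% set against it. Fewer reads or weaker enrichment would also lower this recurrence, so the test cannot decide on this explanation. Replicate 2 calls were weaker, with a median -log10 q of 1.26 against 2.62 in replicate 1. The highest -log10 p was 16.9 against 26.8. Of all protein-coding genes at 10% in replicate 2, 97.8% also reached it in replicate 1. These values go with fewer reads or weaker enrichment but do not separate the causes. The explanation stays open, and read depth was not analysed here.

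Chromosome X had few peaks. A lower number of active genes on X may be proposed, but 8 X-linked housekeeping, ribosomal and complex I genes had a mean replicate 1 coverage of 2.59% ± 5.43 (SD over genes), against 24.9% ± 17.9 for 130 autosomal members. This is 10.4% of the autosomal level, and no draw of 8 autosomal members out of 10000 was as low, though these are only 8 genes, most of them short. If instead X genes carry a weaker signal, as with a single active X per cell, X should lose more to a stricter threshold. The ratio of X to autosomes fell to at most 0.650 of its value in both replicates with only peaks of -log10 p of at least 5. At levels of at least 4, 5 and 6, the ratio was 0.110, 0.0909 and 0.0483 in replicate 1. In replicate 2, with only 149 X peaks, it was 0.0444, 0.0297 and 0.0299, against 0.0456 with all peaks. A weaker signal under the peak threshold would give this fall. Fewer active genes, with weak calls a larger part of the peaks on X, would give it too, so the test does not separate these. The median fold enrichment of X and autosomal peaks was close, at 3.12 against 3.25 in replicate 1 and 3.06 against 3.07 in replicate 2. Nor does the test separate a single active X from other reasons for a weaker signal, such as X copy number or the control. Those were not analysed here.

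Of lung cell type markers 5.52% were marked, and of all protein-coding genes 10.1%, a difference that was not itself tested. Short marker genes as the cause of a low mean are argued against by the mean coverage, which in replicate 1 was at the 0.02nd percentile of random lists of matched length and in replicate 2 at the 0.78th. The median, the measure fixed before the data were examined, was not low (72.8th percentile in replicate 1) and decides nothing on gene length. That each type is only a part of the tissue, with signal under the threshold, stays open. Lung markers had a pooled peak 6.96 times as often as markers of other organs. But a peak lay at 64.8% of lung markers in replicate 1 and 47.6% in replicate 2, against 49.5% and 42.9% of all protein-coding genes. These shares were not matched on gene length. In replicate 1 the share of genes with a peak was 15.6% under 5 kb and 69.9% at 50 to 100 kb. Whether lung markers are short of peaks for their length was therefore not settled.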

How the results depend on the processing

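The count of marked genes among those overlapping no other gene, and the use of list means, were alternatives chosen after seeing the data. Directions held under every alternative run: more coverage in genes than outside them, more toward the 3' end, and less on X. The mean ratio on X was 0.0603 with only peaks of -log10 p of at least 5 and 0.0532 with equal numbers, against 0.0959. The spread of the 2 replicates (SD 0.0711) is too wide to call this ratio stable. Sizes depended on the peak threshold and on the level set per gene. With only peaks of -log10 p of at least 5, shared bases fell to 9.17%. Overlap of peaks fell to 16.6% of replicate 1 and 66.0% of replicate 2 peaks. Under this setting 517 genes were marked, and by their medians 2 lists were above random lists in place of 5. Genic over intergenic coverage was then 40.7, the downstream to upstream ratio 2.75 and rho 0.757. With equal numbers of peaks, overlap was 41.8%, 50.3% and 18.0% of bases, genic over intergenic coverage 35.5 and rho 0.853. The marked genes then numbered 2050, all of them among the 2214, which follows from the setting, since it only removes replicate 1 peaks. Requiring 50% of a peak's bases gave overlaps of 12.5% and 60.5%, and joining peaks within 1 kb gave 33.6%, 70.3% and 22.1% of bases. Marked genes numbered 4304 at 5% and 476 at 20% of the span, 4602 with the replicated list, 6581 with the pooled list, 3368 over the downstream 50% of each gene and 1017 among genes overlapping no other. Leaving out replicate 1 gave 2263 and leaving out replicate 2 gave 6513. Coverage of protein-coding genes over the rest of the genome was 34.4, the downstream to upstream ratio in genes of at least 20 kb was 1.93, and rho in genes of at least 10 kb was 0.907. The cause of these shifts was not tested beyond the fewer peaks or bases that the settings keep. For marked members of single lists, stricter peaks changed the count by more than 1.5 times in 12 of 31 lists, all to fewer. Many of the 31 lists had no marked member to lose and were counted as unchanged. Of the lists with a marked member, only lung branching signals kept its count, 2, with stricter peaks. The replicated list changed the count in 13 lists and leaving out replicate 2 in 15, all to more. Leaving out replicate 1 changed none by that much. Depth, which was not analysed here, limits which genes can reach the threshold.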

Other observations

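The families and single genes in this part were chosen after their values were seen, while the bounds of the test of zinc finger genes were set before. Families defined by symbol differed in how often their genes were marked, over 108 families of at least 20 protein-coding genes. The Ddx genes, mostly RNA helicases, were marked most often, at 22 of 37 (59.5%), against 10.1% of all protein-coding genes. They were followed by Nup genes of the nuclear pore (9 of 21), Eif translation initiation factors (22 of 55), Gtf general transcription factors (9 of 23) and Polr subunits of RNA polymerases (9 of 28). In 30 of the families no gene was marked, among them 39 Prss proteases, 26 Pde phosphodiesterases and 34 Rhox homeobox genes. Families were not matched on gene length or set against random lists.

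Single genes known for their roles in lung ranged widely in coverage. The surfactant protein genes Sftpc and Sftpa1, of 3.13 kb and 4.67 kb, had no base under a peak in either replicate. Sftpb was covered to 8.45% and 8.74% and Sftpd to 4.62% and 1.62%. Among matrix genes Eln, which encodes elastin, was at 24.1% and 5.15%, Col1a1 at 14.6% and 2.5% and Col1a2 at 15.7% and 0.931%. Others were lower: Col3a1 was at 6.63% and 0, Col5a2 at 0.824% and 0.309%, and Lum had no peak. In endothelium the growth factor receptor gene Kdr was at 19.6% and 1.17% and Eng at 24.3% and 3.94%, but Pecam1 was at 2.39% and 0.512% and Flt1 at 1.72% and 0.423%. Of the imprinted noncoding genes H19 had no peak, while Meg3 was at 9.60% and 0.683%, Airn at 5.38% and 1.13% and Kcnq1ot1 at 2.04% and 0.908%.

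On chromosome X the genes with the highest summed coverage were Kdm5c (43.4% and 6.14%), Flna (32.2% and 4.69%) and Ddx3x (33.4% and 3.34%). Kdm5c and Ddx3x are known to be expressed from both X copies in female cells, but whether that bears on their coverage was not tested. On X, 251 genes had a peak in replicate 1 and 76 in replicate 2. At equal numbers of peaks, the general epithelial list was the only list of a cell type of the lung itself with higher mean coverage in replicate 2 than in replicate 1 (1.66% against 0.397%). Most of this came from Esrp2 (16.1% against 0), which overlaps another protein-coding gene, and Krt18 (5.46% against 0). With all peaks the list was at 3.17% in replicate 1 and 1.66% in replicate 2. Esrp2 was then at 19.7% and 16.1%, and Krt18 at 2.75% and 5.46%.

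Zinc finger genes may carry the mark more at their 3' end than other marked genes do. This was tested against the alternative that they are marked along the gene like others of their length. In 74 marked Zfp genes of at least 5 kb the 3'-most of 3 equal parts held 53.1% ± 19.2 (SD over genes) of the covered bases in replicate 1, against a mean of 48.0% in length-matched marked genes, and 59.7% ± 26.7 against 49.7% in replicate 2. These means lay at the 99.3rd and 99.98th percentiles of 10000 matched draws, which argues against the same 3' share as in marked genes of like length. The draws were not matched on coverage or on the layout of exons, so a part played by either was not separated. The differences are small beside the spread between genes, and no second data set was used to test them.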
